A study of Mus musculus with 12 samples.

How the data were processed

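Total RNA from the livers of 12 mice, 4 groups of 3 biological replicates, was measured with 1 array per mouse. Per the labels' protocols, RNA was extracted with the Perfect Pure RNA Tissue kit, and 100 ng was amplified and biotin-labelled with the Ambion Whole Transcript Expression kit and the Affymetrix terminal labelling kit. Per the submitters' processing notes, the authors made the signal intensity values with RMA in Affymetrix Expression Console 1.2.1.20. RMA corrects background, normalizes between arrays and summarises probes into probe sets. Dates of hybridization and scanning, the allotment of mice to groups, the dose of virus and of T3, and the number of probes behind a probe set are not given in the sources used here.

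The deposited table holds 33649 probe sets on 12 arrays. Its intensity values, as deposited, are whole numbers (100% equal their rounded value) from 6 to 17590, with array medians of 96 to 108, so they are on the linear scale. The plan written before the data were examined assumed log2 values. Log2 was therefore taken, with no pseudocount, since the lowest value is 6. Values were not normalized again. No probe set had been removed by a detection filter that the sources state, and detection calls are not used here.

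Probe sets were matched to genes by the symbols of the array's annotation: 23521 carried 1 symbol, 1814 several and 8314 none. Where a gene had more than 1 probe set (1082 genes), the one with the highest mean signal over all arrays was used, which left 22180 genes. Probe sets with no or several symbols were tested in a further fit and adjustment over all 33649 probe sets, and their number is in the closing part. Of the genes tested 6039 had a mean signal under 64, where array signals lie near background. Positions on the genome were not used here.

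Groups followed the labels: Ad-GFP or Ad-TRb virus, with saline or T3. For the Ad-TRb groups the Thrb signal goes against the label under T3, so they are called livers labelled Ad-TRb. Comparisons were T3 against saline after each virus, Ad-TRb against Ad-GFP under each treatment, and the interaction of virus and T3. Each used limma 3.58.1 in R 4.3.3: lmFit with 1 mean per group on all 12 arrays, then eBayes with a single prior variance (prior degrees of freedom 4.923, prior variance 0.01741, residual degrees of freedom 8). Benjamini-Hochberg adjustment covered the 22180 genes, with a threshold of adjusted p under 0.05, and all tests were two-sided. Errors beside log2 values are limma's moderated SE, and errors beside signals are SD. Thrb also had an exact two-sided permutation test of 3 against 3 arrays. Tables and figures used Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

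The genes named follow a rule written before the data were examined, as were the comparisons, the gene lists and the alternatives. They are the 10 largest increases and decreases per pairwise comparison (5 each way for the interaction) among genes past the threshold whose arrays do not overlap between groups. To these come Thrb, Thra, Thrsp, Dio1, Me1 and Cyp7a1, and up to 4 members of each list with the smallest p. Where genes are given as examples, those whose call ends in an alternative were mostly passed over, so the examples are firmer than their list.

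Of 31 gene lists written from general knowledge, with 453 symbols of which 405 were measured, 30 were tested and the erythroid list, with fewer than 3 members measured, was left out. Camera with a preset correlation of 0.01 compared each list with the other genes, adjusted over the lists of a comparison. Camera with an estimated correlation was run beside it, and so was fry, which asks whether a list's genes move on balance one way, or in its mixed form whether they change in either direction. Members past the threshold are counted over all genes and, as risen and fallen, adjusted over the list alone. Of the cell type lists, stellate cell markers measured 11 genes, macrophage 17, endothelial 9, hepatocyte 11, neutrophil 10, T and NK cell 15, cholangiocyte 5 and B and plasma cell 6. Of these 11, 16, 9, 11, 5, 11, 4 and 4 had a mean signal of at least 64 in Ad-GFP saline livers, and 2 hepatocyte markers are in another list as well. Lists of other kinds share genes too. The list of genes reported as T3-induced holds Thrsp, Me1, Acly and Fasn of lipogenesis and Cyp7a1 of bile acid synthesis, among others. Lists that pass together are therefore not independent.

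Agreement of responses across genes was described by Pearson and Spearman correlation and a total least squares slope over genes called in either comparison, with a jackknife over arrays. Numbers of genes called in both are given beside those for independent lists. For the pair that shares the Ad-GFP saline arrays, 100 draws of unchanged groups gave the correlation that the sharing alone makes.

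The alternatives were median centring, cyclic loess between arrays, genes at or above the median signal, every probe set, the mean of a gene's probe sets, an intensity trend with robust eBayes, array weights, the replicate number as a block, each array left out in turn, and only the 6 arrays compared. Further ones were a change of at least 1.5-fold, adjusted p under 0.01, an estimated correlation, fry, and all genes tested for the correlations. The pipeline was tested on simulated data of 22180 genes with 50 changed genes per fold. For T3 in Ad-GFP livers it recovered 66% of 1.5-fold, 94% of 2-fold and 100% of 4-fold changes, with 4.26% false calls. For the interaction it recovered 16%, 82% and 100%, with 5.7% false calls.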

Results

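Liver RNA of 12 mice was measured on a whole-transcript gene array, with 1 array per mouse. All mice were heterozygous for the bacterial biotin ligase BirA on an FVB background and were 9 to 10 weeks old. For 3 weeks they ate a diet containing propylthiouracil (PTU), a drug that blocks thyroid hormone synthesis, per the labels' protocols. An adenovirus was then given by tail vein. It carried green fluorescent protein alone (Ad-GFP) or, per the series title, GFP and a biotinylated thyroid hormone receptor beta (Ad-TRb). The mice next received saline or triiodothyronine (T3, the active thyroid hormone) by intraperitoneal injection over 4 days. The 4 groups held 3 mice each, which the labels call biological replicates. The comparisons ask how the hormone changes liver transcripts after either virus, and what the receptor virus changes with and without the hormone.

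Signals ran from 6 to 17590, and the median signal of an array lay between 96 and 108. Each array correlated with the other arrays of its group at a mean r of 0.989 to 0.996 across genes. Labelled Ad-TRb T3 array 2 stood apart most, with the lowest mean r and a residual SD of 0.197 on the log2 scale, against 0.107 to 0.17 in the others. Without it, 2018 genes rather than 1568 passed for T3 in Ad-GFP livers and 2166 rather than 1681 between viruses under saline. Neither comparison contains it, but the residual variance of the fit does. The first principal component held 54.2% of the variance and set the arrays labelled Ad-TRb with T3 apart from the 3 other groups. The number of arrays limits the precision: the median SE of a log2 change was 0.109. An exact two-sided permutation test of 3 against 3 arrays cannot give a p below 0.1, so calls across genes rest on limma with Benjamini-Hochberg adjustment over 22180 genes.

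Thrb, the receptor gene that the Ad-TRb virus carries, was read by 1 probe set. Under saline its mean signal was 1171 ± 76.7 (SD, n = 3) after Ad-GFP and 1520 ± 200.1 in livers labelled Ad-TRb. That difference of 0.37 ± 0.13 (log2, SE) did not pass (limma adjusted p = 0.109, exact permutation p = 0.1). Under T3 the signal was 1048 ± 116 after Ad-GFP and 430.3 ± 60.1 in livers labelled Ad-TRb, where Thrb was lower by 2.44-fold (-1.29 ± 0.13, adjusted p = 6.13e-06, exact permutation p = 0.1). The signal under T3 therefore goes against the virus label, and these mice are called livers labelled Ad-TRb throughout. Every direction drawn between the viruses rests on that label. So do the T3 comparisons and the interaction, which would change if the virus labels of the T3 groups were exchanged. Where the probe set lies relative to the delivered sequence is not given in the sources used here, so it may read the mouse's own gene alone. Thra, the gene of the other T3 receptor, had mean signals of 192, 182, 204 and 135 in Ad-GFP saline, Ad-GFP T3, labelled Ad-TRb saline and labelled Ad-TRb T3 livers.

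**Figure D1:**
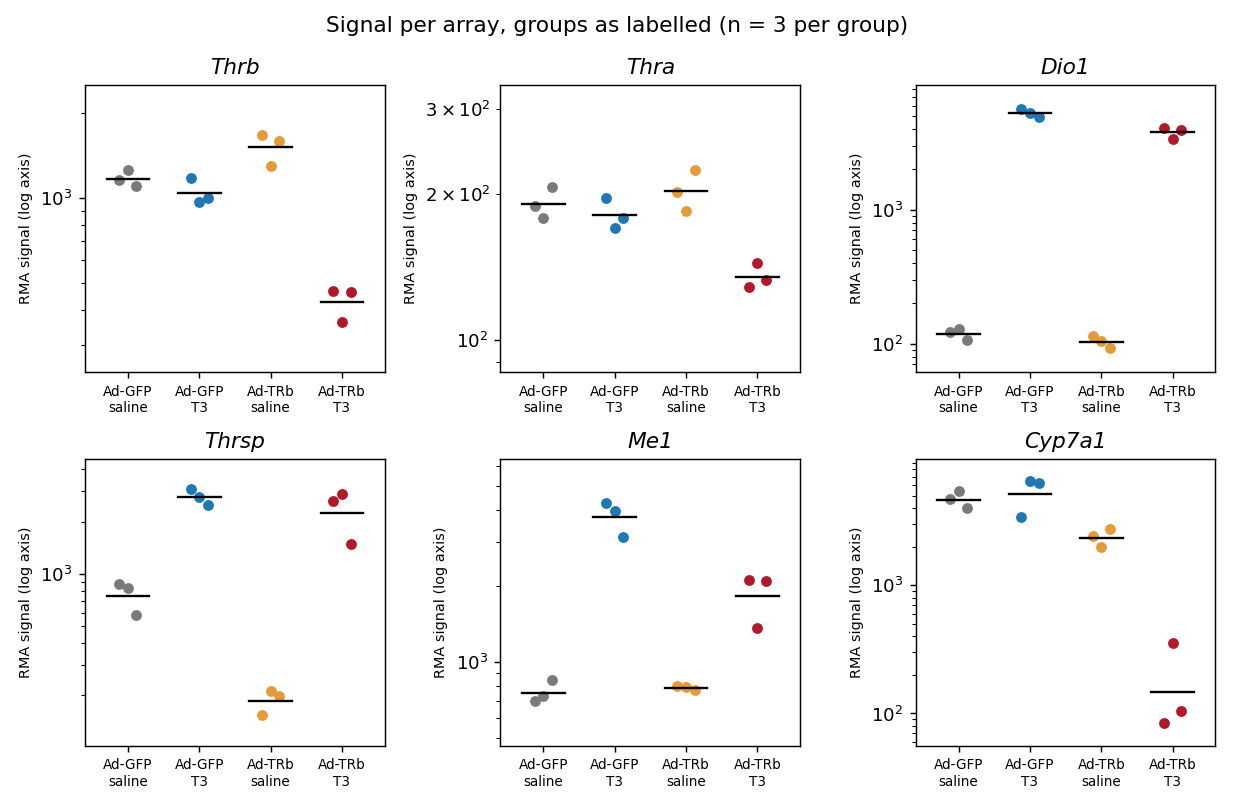
Signal per array (points, log axis, n = 3 a group) and geometric group mean (line) for 6 genes named in advance, with groups as labelled. Thrb is lowest and Cyp7a1 lowest in livers labelled Ad-TRb with T3, while Dio1 is high in both T3 groups.

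In Ad-GFP livers, T3 raised Dio1, Thrsp and Me1 and lowered Cyp4a14 and Serpina7. Dio1, the liver deiodinase that removes iodine from thyroid hormones, rose 44.6-fold (log2 5.48 ± 0.11, SE, n = 3 against 3), from a mean signal of 119 ± 10.8 (SD) to 5297 ± 388. Thrsp, a regulator of fatty acid synthesis, rose 3.71-fold (1.89 ± 0.22), and Me1, the malic enzyme that supplies NADPH to that pathway, rose 4.96-fold (2.31 ± 0.16). Cyp4a14, a fatty acid hydroxylase, fell by 5.48 on the log2 scale (SE 0.56, 44.7-fold), and Serpina7, the thyroxine-binding globulin of plasma, was 10.0-fold lower. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, did not pass, with mean signals of 4686 ± 691 under saline and 5398 ± 1723 under T3 (log2 difference 0.16 ± 0.42, adjusted p = 0.91).

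Of 22180 genes, 1568 passed adjusted p under 0.05 in limma, 811 higher and 757 lower with T3. By at least 4-fold, 33 were higher and 12 lower. The arrays of both groups did not overlap for 27.4% of genes, where chance gives 10% for 3 against 3. Other large increases were those of 9030619P08Rik (7.18 ± 0.15), Sult3a1 (6.03 ± 0.29) and Ugt2b37 (4.50 ± 0.19), a sulfotransferase and a glucuronosyltransferase among them, and Cyp17a1 (4.30 ± 0.23), a steroid hydroxylase. Slc22a7 (3.86 ± 0.24), an organic anion transporter, and Tlcd2 (3.52 ± 0.14) also rose. Falls included Etnppl (-3.10 ± 0.15), a phospholyase of ethanolamine phosphate, Abcc3 (-2.39 ± 0.16), an exporter of bile acid and drug conjugates, and Nr4a1 (-2.25 ± 0.23), an orphan nuclear receptor. Members of the Cyp, Sult, Ugt, Mup, Ces and Slc22a families have near-identical copies, so which member a probe set reads is uncertain here and in each later comparison. Of 115 other probe sets of the genes called here, 75.7% had the same sign as the one used. The share was 73.3% for T3 in livers labelled Ad-TRb and 77.5% between viruses under saline. Between viruses under T3 it was 74.2%, and for the interaction 68.2%. These other probe sets were not filtered on signal. The number of genes past the threshold moved by more than 1.5 times without single arrays, to 983, 934 and 914 without Ad-GFP saline arrays 1, 2 and 3 and to 1016 and 1029 without Ad-GFP T3 arrays 1 and 2. It was 3129 with array weights, 763 with a change of at least 1.5-fold required, and 738 at adjusted p under 0.01.

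Of 30 fixed gene lists, 13 passed camera, 9 shifted up and 4 down. Among genes reported elsewhere as T3-induced in liver, 8 of 17 measured members rose, 0 fell and 9 did not pass, against 8 and 0 adjusted over the list alone. Their median was 0.49 (camera adjusted p = 3.16e-10, and adjusted p = 0.0398 with an estimated correlation). Besides Dio1, Thrsp and Me1 these were led by Idh3a (2.00 ± 0.14), a subunit of mitochondrial isocitrate dehydrogenase, and Gpd2 (1.95 ± 0.12), the mitochondrial glycerol phosphate dehydrogenase. This was the 1 list of the comparison whose call held with an estimated correlation. In the lipogenesis list 6 of 20 measured members rose, 0 fell and 14 did not pass, against 12 and 0 adjusted over the list alone. Pnpla3 (2.70 ± 0.40), a lipid droplet protein, and Mlxipl (0.80 ± 0.12), the carbohydrate-responsive factor ChREBP, rose with Me1 and Thrsp (camera adjusted p = 7.34e-08, and adjusted p = 0.233 with an estimated correlation). For cholesterol synthesis and uptake, 4 of 19 measured members rose, 0 fell and 15 did not pass, against 12 and 0 adjusted over the list alone. Sqle (2.27 ± 0.28) and Sc5d (1.40 ± 0.14), enzymes of sterol synthesis, rose (camera adjusted p = 8.52e-09, and adjusted p = 0.31 with an estimated correlation). Bile acid genes shifted up too: 6 of 16 measured members rose, 0 fell and 10 did not pass, against 6 and 0 adjusted over the list alone. Cyp27a1 (0.96 ± 0.11) and Cyp7b1 (1.14 ± 0.20) of the acidic pathway rose (camera adjusted p = 1.59e-05, and adjusted p = 0.182 with an estimated correlation). Abcg5 (0.75 ± 0.10) and Abcg8 (0.79 ± 0.14), which together form a sterol exporter, also did.

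Fatty acid oxidation and ketogenesis shifted down, and 0 of 20 measured members rose, 5 fell and 15 did not pass, against 0 and 5 adjusted over the list alone. Acot1 (-1.74 ± 0.23), an acyl-CoA thioesterase, and Acadm (-0.52 ± 0.10), the medium-chain acyl-CoA dehydrogenase, fell beside Cyp4a14 (camera adjusted p = 9.68e-05, and adjusted p = 0.291 with an estimated correlation). Oxidative phosphorylation shifted up by a median of 0.13: 5 of 23 measured members rose, 0 fell and 18 did not pass, against 6 and 0 adjusted over the list alone. Cox5a (0.76 ± 0.08), Cyc1 (0.44 ± 0.07) and Cycs (0.41 ± 0.07) rose (camera adjusted p = 1.22e-06, and adjusted p = 0.24 with an estimated correlation). In xenobiotic metabolism 1 of 21 measured members rose, 9 fell and 11 did not pass, against 1 and 12 adjusted over the list alone. Nqo1 (-1.36 ± 0.23), Cyp1a2 (-0.77 ± 0.13) and Fmo5 (-0.67 ± 0.09), drug-handling enzymes, fell (camera adjusted p = 0.000111, and adjusted p = 0.182 with an estimated correlation). Female-biased liver genes shifted up: 7 of 13 measured members rose, 2 fell and 4 did not pass, against 9 and 3 adjusted over the list alone. Sult3a1 and Cyp17a1 rose and Acot3 (-2.22 ± 0.27) fell (camera adjusted p = 0.000111, and adjusted p = 0.182 with an estimated correlation). In the growth hormone and IGF axis 4 of 12 measured members rose, 0 fell and 8 did not pass, against 4 and 0 adjusted over the list alone. Stat5a (1.12 ± 0.12) and Stat5b (0.78 ± 0.12), signal transducers of the growth hormone receptor, rose (camera adjusted p = 0.00589, and adjusted p = 0.291 with an estimated correlation).

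Cell cycle genes shifted down: 1 of 23 measured members rose, 6 fell and 16 did not pass, against 1 and 7 adjusted over the list alone. The replication helicase subunits Mcm3 (-0.93 ± 0.14), Mcm4 (-0.98 ± 0.17) and Mcm6 (-0.99 ± 0.19) fell, while Ccnd1 (1.02 ± 0.20), cyclin D1, rose (camera adjusted p = 0.00493, and adjusted p = 0.728 with an estimated correlation). Among p53 targets 0 of 10 measured members rose, 6 fell and 4 did not pass, against 1 and 8 adjusted over the list alone. Cdkn1a (-0.62 ± 0.12), the cyclin kinase inhibitor p21, and Sesn2 (-0.73 ± 0.12) fell (camera adjusted p = 1.56e-06, and adjusted p = 0.182 with an estimated correlation). Genes of ER stress and the amino acid response shifted up, and 4 of 14 measured members rose, 0 fell and 10 did not pass, against 5 and 0 adjusted over the list alone. Creld2 (1.10 ± 0.21) was among them (camera adjusted p = 0.000271, and adjusted p = 0.182 with an estimated correlation). Macrophage markers moved with these groups: 4 of 17 measured members rose, 0 fell and 13 did not pass, against 6 and 0 adjusted over the list alone. Vsig4 (1.31 ± 0.23), a Kupffer cell receptor, rose, and the median was 0.46 (camera adjusted p = 2.45e-05, and adjusted p = 0.266 with an estimated correlation). Hepatocyte markers had a median of 0.09 and stellate cell markers of 0.17, and neither list passed (camera adjusted p = 0.353 and 0.26). The other lists that did not pass included the genes reported as T3-repressed in liver (median 0.05, camera adjusted p = 0.913).

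In livers labelled Ad-TRb, T3 raised Sult1e1, Dio1, Thrsp and Me1 and lowered Cyp7a1, Cyp4a14 and Thrb. Sult1e1, the estrogen sulfotransferase, rose 88.4-fold (log2 6.47 ± 0.18, SE, n = 3 against 3), and Dio1 rose 36.8-fold (5.20 ± 0.11), to a mean signal of 3800 ± 357 (SD). Thrsp rose by 3.59 ± 0.22 on the log2 scale and Me1 2.31-fold (1.21 ± 0.16). Cyp7a1 was 16.1-fold lower (-4.01 ± 0.42), at 182 ± 152 against 2375 ± 375 under saline, and Cyp4a14 was 86.1-fold lower (-6.43 ± 0.56). Thrb itself was 3.54-fold lower with T3 in these livers (-1.82 ± 0.13, adjusted p = 2.46e-07).

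Of 22180 genes, 6908 passed adjusted p under 0.05, 3800 higher and 3108 lower, and 137 were higher and 171 lower by at least 4-fold. The arrays did not overlap for 39.1% of genes, against 10% by chance. Increases next in size included 9030619P08Rik (6.13 ± 0.15), Cep126 (5.87 ± 0.14), a centrosomal protein, Nradd (5.74 ± 0.18), a death-domain membrane protein, Sult2a1 (5.31 ± 0.47) and Prom1 (5.25 ± 0.22), the membrane protein CD133. Falls included Ces1f (-5.99 ± 0.12), a carboxylesterase, Hsd17b6 (-4.88 ± 0.28), a steroid dehydrogenase, Inmt (-4.70 ± 0.20), a methyltransferase, and Cyp2c23 (-4.59 ± 0.10). Keg1, an acyltransferase-like gene, fell by 5.22 at its main probe set, while its other probe set gave -1.38. With a change of at least 1.5-fold required, 3304 genes passed.

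By camera 9 lists passed, 6 up and 3 down, and 0 held with an estimated correlation, while fry called a one-way shift in 18. Of the genes reported as T3-induced in liver, 8 of 17 measured members rose, 4 fell and 5 did not pass, against 8 and 4 adjusted over the list alone. Idh3a rose by 2.91 ± 0.14 and Gpd2 by 2.28 ± 0.12, and Cyp7a1 fell (camera adjusted p = 0.0237, and adjusted p = 0.558 with an estimated correlation). Genes of thyroid hormone transport, deiodination and receptors shifted down by a median of -0.59: 2 of 15 measured members rose, 11 fell and 2 did not pass, against 2 and 12 adjusted over the list alone. Thra (-0.59 ± 0.10), Serpina7 (-4.32 ± 0.38), Slco1a4 (-2.41 ± 0.23), an anion uptake transporter, and Ttr (-0.39 ± 0.08), the transthyretin carrier, fell along with Thrb (camera adjusted p = 0.000688, and adjusted p = 0.141 with an estimated correlation). In lipogenesis 12 of 20 measured members rose, 4 fell and 4 did not pass, against 12 and 4 adjusted over the list alone. Pnpla3 (4.13 ± 0.40), Elovl6 (3.31 ± 0.18), a fatty acid elongase, and Scd1 (1.28 ± 0.12), the stearoyl-CoA desaturase, rose (camera adjusted p = 0.00772, and adjusted p = 0.627 with an estimated correlation). For cholesterol synthesis and uptake, 10 of 19 measured members rose, 1 fell and 8 did not pass, against 10 and 1 adjusted over the list alone. Sqle (2.08 ± 0.28) and Srebf2 (1.02 ± 0.16) rose and Ebp (-0.83 ± 0.09), a sterol isomerase, fell (camera adjusted p = 0.0176, and adjusted p = 0.627 with an estimated correlation).

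Fatty acid oxidation and ketogenesis shifted down by a median of -0.87: 1 of 20 measured members rose, 18 fell and 1 did not pass, against 1 and 18 adjusted over the list alone. The beta-oxidation enzymes Acadm (-1.21 ± 0.10) and Acaa2 (-0.98 ± 0.09) fell beside Cyp4a14 (camera adjusted p = 1.32e-07, and adjusted p = 0.308 with an estimated correlation). In xenobiotic metabolism 4 of 21 measured members rose, 14 fell and 3 did not pass, against 5 and 14 adjusted over the list alone. Fmo5 (-1.99 ± 0.09), Aldh1a1 (-1.83 ± 0.09) and Ugt2b1 (-2.22 ± 0.12) fell, while Sult1e1 rose (camera adjusted p = 0.000914, and adjusted p = 0.308 with an estimated correlation). Female-biased liver genes shifted up, and 7 of 13 measured members rose, 2 fell and 4 did not pass, against 7 and 2 adjusted over the list alone (camera adjusted p = 0.0144, and adjusted p = 0.562 with an estimated correlation). Cell cycle genes shifted up: 6 of 23 measured members rose, 1 fell and 16 did not pass, against 6 and 1 adjusted over the list alone. Ccnd1 (1.97 ± 0.20) and Bub1 (2.34 ± 0.34), a mitotic checkpoint kinase, rose (camera adjusted p = 0.00812, and adjusted p = 0.627 with an estimated correlation). In the list of ER stress and the amino acid response 8 of 14 measured members rose, 0 fell and 6 did not pass, against 8 and 0 adjusted over the list alone. Asns (2.10 ± 0.15), asparagine synthetase, Chac1 (2.24 ± 0.26) and Xbp1 (0.65 ± 0.12) rose (camera adjusted p = 0.00245, and adjusted p = 0.308 with an estimated correlation). Bile acid genes did not pass camera as a list (median -0.47, adjusted p = 0.106, and 0.049995 by fry), and 3 of 16 measured members rose, 8 fell and 5 did not pass, against 5 and 9 adjusted over the list alone. Cyp27a1 rose by 2.73 ± 0.11, while Cyp8b1 (-1.95 ± 0.22) and Slco1b2 (-2.58 ± 0.21), a bile acid uptake transporter, fell. Beside these groups, liver endothelial markers had a median of 0.44, where 6 of 9 measured members rose, 0 fell and 3 did not pass, against 6 and 0 adjusted over the list alone (camera adjusted p = 0.0527, and 0.015301 by fry). Macrophage markers had one of 0.32, where 3 of 17 measured members rose, 0 fell and 14 did not pass, against 3 and 0 adjusted over the list alone (camera adjusted p = 0.0949). Stellate cell and matrix markers had one of 0.25, where 2 of 11 measured members rose, 1 fell and 8 did not pass, against 2 and 1 adjusted over the list alone (camera adjusted p = 0.227). Lyve1 (1.37 ± 0.19), Cd14 (1.72 ± 0.25) and Acta2 (1.81 ± 0.18), markers of sinusoidal endothelium, macrophages and activated stellate cells, rose.

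**Figure D2:**
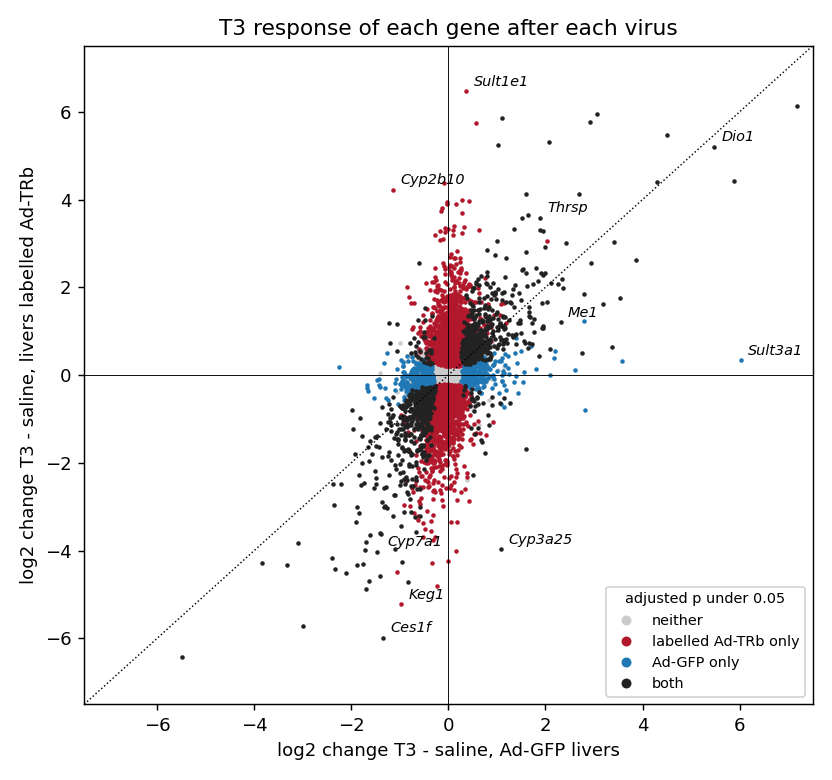
Log2 T3 response of each of 22180 genes in Ad-GFP livers (x axis) and in livers labelled Ad-TRb (y axis), coloured by which comparison passed adjusted p under 0.05, with equal responses on the dotted line. Dio1 lies near that line, Cyp7a1 and Sult3a1 lie below it, and Sult1e1 and Cyp2b10 lie above it.

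The T3 responses after both viruses overlapped more than independent lists would, and the difference itself passed for 3284 genes. Genes called in both comparisons, which share no array, were both higher for 519 (139 for independent lists) and both lower for 473 (106), and 35 and 35 went in opposite directions (114 and 130). Across the 7414 genes called in either, Pearson's r was 0.528 (Spearman 0.503), a value across genes, which are not independent replicates, with a jackknife SE over arrays of 0.0712. The total least squares slope of the response in livers labelled Ad-TRb on that in Ad-GFP livers was 3.14 ± 0.265 (jackknife SE). Of these genes 5846 were called only in livers labelled Ad-TRb. The slope therefore takes in the wider spread of changes there and does not measure a stronger response of the same genes. The 811 genes that T3 raised in Ad-GFP livers had a median of 0.55 there and 0.52 in livers labelled Ad-TRb, and the 757 it lowered had medians of -0.59 and -0.53. Both sets were chosen by passing in Ad-GFP livers, which alone enlarges the medians there. The near values therefore do not show that the responses were equal. Without Ad-GFP saline arrays 2 and 3 the genes called in the same direction numbered 621 and 656 rather than 992. Those called in opposite directions numbered 35, 42 and 32 without Ad-GFP saline arrays 1, 2 and 3 and 40 and 40 without Ad-GFP T3 arrays 1 and 2, rather than 70.

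The test of the difference itself, an interaction of virus and T3, passed for 3284 genes, with a higher T3 effect in livers labelled Ad-TRb for 1850 and a lower one for 1434. Sult1e1 (6.09 ± 0.26), Cyp2b10 (5.37 ± 0.74), a drug-inducible cytochrome, Nradd (5.17 ± 0.26) and Tff2 (4.47 ± 0.14), a secreted trefoil peptide, were among the largest differences upward. Sult3a1 (-5.69 ± 0.41), Cyp3a25 (-5.05 ± 0.31), Ces1f (-4.65 ± 0.17) and Slc22a30 (-4.57 ± 0.28) were among the largest downward. Thrsp responded more in livers labelled Ad-TRb, by 1.70 ± 0.32 (adjusted p = 0.00283), while Me1 (-1.10 ± 0.23), Cyp7a1 (-4.17 ± 0.59) and Thrb (-1.66 ± 0.18) had lower T3 effects there. The difference for Dio1 was -0.28 ± 0.15 and did not pass (adjusted p = 0.276). Thra passed at -0.51 ± 0.14, a call that median centring ended (-0.44, adjusted p = 0.0816). It also ended without Ad-GFP saline arrays 1 and 2 (adjusted p = 0.0551 and 0.0609), Ad-GFP T3 array 1 (0.0600), labelled Ad-TRb saline array 3 (0.0537) or labelled Ad-TRb T3 array 1 (0.0581). Groupings that mix the other arrays but keep the labelled Ad-TRb T3 arrays together gave up to 2580 genes. With array weights 5044 genes passed, and 1703 at adjusted p under 0.01.

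By camera 10 lists passed, 2 with a higher and 8 with a lower T3 effect. The T3 effect was lower in livers labelled Ad-TRb for thyroid hormone transport, deiodination and receptors, where 0 of 15 measured members had a higher and 9 a lower T3 effect, and 6 did not pass, against 0 and 10 adjusted over the list alone. Rxra (-0.71 ± 0.12), the dimer partner of the receptors, and Slco1a4 (-1.96 ± 0.33) were lower (camera adjusted p = 1.41e-06, and adjusted p = 0.0265 with an estimated correlation). This call held under both. For bile acid synthesis and transport 2 of 16 measured members had a higher and 9 a lower T3 effect, and 5 did not pass, against 2 and 11 adjusted over the list alone. Baat (-1.80 ± 0.20) and Cyp8b1 (-1.66 ± 0.32) were examples (camera adjusted p = 8.49e-05, and adjusted p = 0.494 with an estimated correlation). In fatty acid oxidation 1 of 20 measured members had a higher and 7 a lower T3 effect, and 12 did not pass, against 1 and 11 adjusted over the list alone. Hadh (-1.32 ± 0.15) and Vnn1 (-2.66 ± 0.47) were lower (camera adjusted p = 0.000123, and adjusted p = 0.598 with an estimated correlation). In gluconeogenesis and glycogen 1 of 11 measured members had a higher and 3 a lower T3 effect, and 7 did not pass, against 1 and 4 adjusted over the list alone. Gys2 (-2.92 ± 0.23), the liver glycogen synthase, was lower, and the median was -0.35 (camera adjusted p = 0.0417, and adjusted p = 0.677 with an estimated correlation). For xenobiotic metabolism 4 of 21 measured members had a higher and 9 a lower T3 effect, and 8 did not pass, against 4 and 11 adjusted over the list alone (camera adjusted p = 0.00825, and adjusted p = 0.598 with an estimated correlation). Among male-biased liver genes 1 of 14 measured members had a higher and 8 a lower T3 effect, and 5 did not pass, against 1 and 9 adjusted over the list alone (camera adjusted p = 0.000134, and adjusted p = 0.598 with an estimated correlation). The T3 effect was higher for the cell cycle, where 8 of 23 measured members had a higher and 0 a lower T3 effect, and 15 did not pass, against 10 and 0 adjusted over the list alone. Mcm3 (1.23 ± 0.19) and Mcm7 (0.75 ± 0.17) were higher (camera adjusted p = 1.41e-06, and adjusted p = 0.677 with an estimated correlation). It was also higher for p53 targets, where 4 of 10 measured members had a higher and 1 a lower T3 effect, and 5 did not pass, against 7 and 1 adjusted over the list alone. Mdm2 (1.42 ± 0.19) and Cdkn1a (1.04 ± 0.17) were higher (camera adjusted p = 0.00756, and adjusted p = 0.677 with an estimated correlation). The interferon response shifted down as a list, where 0 of 22 measured members had a higher and 4 a lower T3 effect, and 18 did not pass, against 0 and 4 adjusted over the list alone (camera adjusted p = 0.0281, and adjusted p = 0.821 with an estimated correlation). T and NK cell markers did so as well, and 0 of 15 measured members had a higher and 1 a lower T3 effect, and 14 did not pass, against 0 and 0 adjusted over the list alone (camera adjusted p = 0.0315, and adjusted p = 0.733 with an estimated correlation).

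Under saline, livers labelled Ad-TRb had less Thrsp, Elovl6 and Cyp27a1 transcript than Ad-GFP livers and more of Parm1, Anxa2 and Sprr1a. Thrsp was 4.02-fold lower (log2 -2.01 ± 0.22, SE, n = 3 against 3), at a mean signal of 188 ± 30.7 (SD) against 761 ± 155, and Elovl6, a fatty acid elongase, was 4.72-fold lower (-2.24 ± 0.18). Cyp27a1, a sterol hydroxylase of bile acid synthesis, was 3.80-fold lower (-1.93 ± 0.11). Parm1, a mucin-like membrane protein, was 6.99-fold higher (2.81 ± 0.15), Anxa2, an annexin, 5.47-fold higher (2.45 ± 0.35) and Sprr1a, an epithelial envelope protein, 5.90-fold higher (2.56 ± 0.44). Dio1 (adjusted p = 0.323), Me1 (adjusted p = 0.887) and Cyp7a1 (log2 -0.98 ± 0.42, adjusted p = 0.198) did not pass.

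In all 1681 genes passed, 886 higher and 795 lower in livers labelled Ad-TRb, and 12 were higher and 12 lower by at least 4-fold. The arrays did not overlap for 26.2% of genes, against 10% by chance. Further increases included Tinag (2.73 ± 0.22), a basement membrane protein, Elovl7 (2.60 ± 0.28), Ppbp (2.23 ± 0.33), a chemokine, and Slc1a4 (2.20 ± 0.15), an amino acid transporter. Slc7a11, the cystine transporter, was higher by 2.55 ± 0.45, while its other probe set gave 0.25 at a dim mean log2 signal of 3.85. Falls included Mug-ps1 (-3.68 ± 0.28), Rgs16 (-3.00 ± 0.37), a regulator of G protein signalling, Slc25a47 (-2.57 ± 0.19), a mitochondrial carrier of liver, Pglyrp2 (-2.18 ± 0.21) and Apof (-2.06 ± 0.11). Without single arrays the count moved by more than 1.5 times, to 878 and 850 without Ad-GFP saline arrays 1 and 2 and to 1066 without labelled Ad-TRb saline array 2. It was 2544 with array weights, 832 with at least 1.5-fold required, and 727 at adjusted p under 0.01.

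By camera 17 lists passed, 7 up and 10 down, and 0 held with an estimated correlation, while fry called a one-way shift in 11. In lipogenesis 1 of 20 measured members rose, 11 fell and 8 did not pass, against 1 and 12 adjusted over the list alone. Agpat2 (-1.32 ± 0.09) and Dgat2 (-0.94 ± 0.11), both of triglyceride synthesis, fell beside Thrsp and Elovl6, at a list median of -0.80 (camera adjusted p = 3.58e-10, and adjusted p = 0.0991 with an estimated correlation). Bile acid synthesis and transport shifted down: 0 of 16 measured members rose, 6 fell and 10 did not pass, against 1 and 11 adjusted over the list alone. Cyp8b1 (-1.67 ± 0.22), Akr1d1 (-1.45 ± 0.16) and Slc27a5 (-0.97 ± 0.19) fell (camera adjusted p = 5.63e-08, and adjusted p = 0.0776 with an estimated correlation). In gluconeogenesis and glycogen 0 of 11 measured members rose, 4 fell and 7 did not pass, against 0 and 8 adjusted over the list alone. Pck1 (-1.74 ± 0.37), the cytosolic PEP carboxykinase, Pygl (-1.60 ± 0.12), glycogen phosphorylase, and Slc2a2 (-1.18 ± 0.20), the liver glucose transporter, fell (camera adjusted p = 2.05e-07, and adjusted p = 0.0776 with an estimated correlation). For the growth hormone and IGF axis 0 of 12 measured members rose, 4 fell and 8 did not pass, against 0 and 6 adjusted over the list alone. Stat5b (-0.95 ± 0.12) and Igfals (-0.78 ± 0.14) fell (camera adjusted p = 1.08e-06, and adjusted p = 0.0776 with an estimated correlation). Genes reported as T3-induced shifted down: 1 of 17 measured members rose, 5 fell and 11 did not pass, against 2 and 10 adjusted over the list alone (camera adjusted p = 0.000175, and adjusted p = 0.0926 with an estimated correlation). Those reported as T3-repressed did so too: 0 of 4 measured members rose, 2 fell and 2 did not pass, against 0 and 2 adjusted over the list alone (camera adjusted p = 0.00159, and adjusted p = 0.0776 with an estimated correlation). Smaller shifts down were those of cholesterol synthesis, where 0 of 19 measured members rose, 1 fell and 18 did not pass, against 0 and 1 adjusted over the list alone (camera adjusted p = 0.0311, and adjusted p = 0.67 with an estimated correlation), and of xenobiotic metabolism, where 1 of 21 measured members rose, 2 fell and 18 did not pass, against 3 and 8 adjusted over the list alone (camera adjusted p = 0.0401, and adjusted p = 0.409 with an estimated correlation). Male-biased liver genes shifted down by a median of -0.26: 0 of 14 measured members rose, 3 fell and 11 did not pass, against 0 and 4 adjusted over the list alone (camera adjusted p = 0.00663, and adjusted p = 0.409 with an estimated correlation).

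Beside these groups, for stellate cell and matrix markers 8 of 11 measured members rose, 0 fell and 3 did not pass, against 10 and 0 adjusted over the list alone. Lrat (1.08 ± 0.13), the retinol acyltransferase of stellate cells, Lum (1.08 ± 0.18) and Timp1 (1.24 ± 0.25) rose, at a median of 0.57 (camera adjusted p = 3.74e-08, and adjusted p = 0.0776 with an estimated correlation). Among neutrophil markers 6 of 10 measured members rose, 0 fell and 4 did not pass, against 8 and 1 adjusted over the list alone. Ngp (1.19 ± 0.20), Ltf (0.89 ± 0.18) and Mpo (0.67 ± 0.14), all granule proteins, rose (camera adjusted p = 1.14e-05, and adjusted p = 0.152 with an estimated correlation). Macrophage markers shifted up: 5 of 17 measured members rose, 0 fell and 12 did not pass, against 10 and 0 adjusted over the list alone. Cd68 (1.06 ± 0.19) and Cd14 (1.28 ± 0.25) rose (camera adjusted p = 2.1e-06, and adjusted p = 0.152 with an estimated correlation). The T and NK cell list shifted up, and 4 of 15 measured members rose, 0 fell and 11 did not pass, against 6 and 0 adjusted over the list alone (camera adjusted p = 0.00368, and adjusted p = 0.398 with an estimated correlation). In the cholangiocyte list 2 of 5 measured members rose, 0 fell and 3 did not pass, against 2 and 0 adjusted over the list alone. Epcam (0.84 ± 0.17) rose there (camera adjusted p = 0.0146, and adjusted p = 0.0926 with an estimated correlation). Hepatocyte markers shifted down by a median of -0.24: 0 of 11 measured members rose, 4 fell and 7 did not pass, against 0 and 6 adjusted over the list alone. Apoa1 (-0.55 ± 0.09) fell (camera adjusted p = 0.000207, and adjusted p = 0.0926 with an estimated correlation). Among p53 targets 1 of 10 measured members rose, 0 fell and 9 did not pass, against 1 and 0 adjusted over the list alone. Sesn2 (0.61 ± 0.12) was the one that rose (camera adjusted p = 0.00575, and adjusted p = 0.398 with an estimated correlation). Interferon response genes shifted up, and 2 of 22 measured members rose, 1 fell and 19 did not pass, against 6 and 1 adjusted over the list alone (camera adjusted p = 0.0401, and adjusted p = 0.67 with an estimated correlation).

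Under T3, livers labelled Ad-TRb had less Cyp7a1, Sult3a1 and Gys2 transcript than Ad-GFP livers and more of Sprr1a, Lmcd1 and Cd24a. Cyp7a1 was 35.5-fold lower (log2 -5.15 ± 0.42, SE, n = 3 against 3), Sult3a1 50.2-fold lower (-5.65 ± 0.29) and Gys2, the liver glycogen synthase, 11.1-fold lower (-3.47 ± 0.16). Sprr1a was 65.2-fold higher (6.03 ± 0.44), Lmcd1, a LIM domain cofactor, 42.6-fold higher (5.41 ± 0.11), and Cd24a, a surface glycoprotein of immature epithelium, 32.9-fold higher (5.04 ± 0.25). Me1 was lower by 2.05-fold (-1.04 ± 0.16) and Dio1 by 1.40-fold (-0.48 ± 0.11), and Thrsp did not pass (-0.31 ± 0.22, adjusted p = 0.348).

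Of 22180 genes, 6552 passed, 3707 higher and 2845 lower, and 129 were higher and 173 lower by at least 4-fold. The arrays did not overlap for 40.8% of genes, against 10% by chance. Other increases were Sult1e1 (5.81 ± 0.18), Nradd (4.92 ± 0.18), Tff2 (4.51 ± 0.10), Prom1 (4.32 ± 0.22) and Muc13 (4.30 ± 0.28), a mucin, and other falls Cyp3a25 (-5.01 ± 0.22), Hsd3b5 (-4.83 ± 0.94), a steroid dehydrogenase of male liver, Inmt (-4.76 ± 0.20) and Ces1f (-4.56 ± 0.12). With a change of at least 1.5-fold required, 3193 genes passed. The virus effects with and without hormone share no array: both were higher for 509 genes (148 for independent lists) and both lower for 440 (102), and 35 and 72 went in opposite directions (114 and 133). Across 7177 genes called in either, r was 0.483 (Spearman 0.499, jackknife SE 0.0887). The slope of the effect under T3 on that under saline was 3.75 ± 1.24 (jackknife SE). It takes in the wider spread of changes under T3, where 5496 of these genes were called alone. The same-direction number was 513 and 481 without Ad-GFP saline arrays 1 and 2 and 585 without labelled Ad-TRb saline array 2, rather than 949. The opposite number was 54, 62 and 69 without Ad-GFP saline arrays 1, 2 and 3, rather than 107.

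By camera 16 lists passed, 4 up and 12 down. In bile acid synthesis and transport 0 of 16 measured members rose, 12 fell and 4 did not pass, against 0 and 13 adjusted over the list alone. Cyp8b1 (-3.33 ± 0.22), Baat (-2.20 ± 0.14), the bile acid conjugating enzyme, and Abcb11 (-1.94 ± 0.16), the bile salt export pump, were lower, at a list median of -1.29 (camera adjusted p = 2.04e-09, and adjusted p = 0.0817 with an estimated correlation). Gluconeogenesis and glycogen shifted down by a median of -1.41: 0 of 11 measured members rose, 10 fell and 1 did not pass, against 0 and 10 adjusted over the list alone. Slc2a2 (-2.01 ± 0.20) and Fbp1 (-1.22 ± 0.13), fructose bisphosphatase, were lower (camera adjusted p = 3.78e-07, and adjusted p = 0.128 with an estimated correlation). In lipogenesis 1 of 20 measured members rose, 12 fell and 7 did not pass, against 2 and 14 adjusted over the list alone. Pklr (-2.41 ± 0.22), liver pyruvate kinase, Srebf1 (-1.45 ± 0.16) and Mlxipl (-1.14 ± 0.12) were lower (camera adjusted p = 0.000176, and adjusted p = 0.373 with an estimated correlation). Among male-biased liver genes 0 of 14 measured members rose, 13 fell and 1 did not pass, against 0 and 13 adjusted over the list alone. Nudt7 (-2.46 ± 0.13) and Selenbp2 (-1.69 ± 0.12) were lower (camera adjusted p = 1.34e-07, and adjusted p = 0.156 with an estimated correlation). Thyroid hormone transport, deiodination and receptors shifted down: 0 of 15 measured members rose, 11 fell and 4 did not pass, against 0 and 12 adjusted over the list alone. Rxra (-0.88 ± 0.09), Slc16a10 (-0.82 ± 0.10), a thyroid hormone transporter, and Slco1a4 (-2.26 ± 0.23) were lower beside Thrb and Thra (-0.42 ± 0.10; camera adjusted p = 4.01e-07, and adjusted p = 0.0266 with an estimated correlation). This was the 1 list of the comparison that held with an estimated correlation. Genes reported as T3-induced were lower too: 1 of 17 measured members rose, 11 fell and 5 did not pass, against 1 and 11 adjusted over the list alone. Klf9 (-0.70 ± 0.13) was an example (camera adjusted p = 0.000635, and adjusted p = 0.156 with an estimated correlation).

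Fatty acid oxidation shifted down on balance: 4 of 20 measured members rose, 11 fell and 5 did not pass, against 4 and 12 adjusted over the list alone. Hadh (-1.32 ± 0.11) and Acadvl (-0.93 ± 0.11) were lower and Pdk4 (2.12 ± 0.17), a pyruvate dehydrogenase kinase, higher (camera adjusted p = 0.00736, and adjusted p = 0.477 with an estimated correlation). In xenobiotic metabolism 3 of 21 measured members rose, 14 fell and 4 did not pass, against 4 and 15 adjusted over the list alone (camera adjusted p = 0.000373, and adjusted p = 0.183 with an estimated correlation). In the growth hormone and IGF axis 1 of 12 measured members rose, 7 fell and 4 did not pass, against 1 and 8 adjusted over the list alone. Ghr (-1.56 ± 0.13) and Igf1 (-0.95 ± 0.18) were lower and Igfbp1 (2.68 ± 0.43) higher (camera adjusted p = 0.0048, and adjusted p = 0.259 with an estimated correlation). For cholesterol synthesis, with a median of -0.20, 0 of 19 measured members rose, 6 fell and 13 did not pass, against 0 and 6 adjusted over the list alone (camera adjusted p = 0.0272, and adjusted p = 0.642 with an estimated correlation). For oxidative phosphorylation, with a median of -0.17, 1 of 23 measured members rose, 5 fell and 17 did not pass, against 1 and 9 adjusted over the list alone (camera adjusted p = 0.042, and adjusted p = 0.559 with an estimated correlation). Cell cycle genes shifted up by a median of 0.86: 16 of 23 measured members rose, 0 fell and 7 did not pass, against 20 and 1 adjusted over the list alone. Mcm3 (1.28 ± 0.14), Ccnd1 (1.49 ± 0.20) and Mcm7 (0.84 ± 0.12) were higher (camera adjusted p = 3.78e-07, and adjusted p = 0.406 with an estimated correlation). Among p53 targets 8 of 10 measured members rose, 1 fell and 1 did not pass, against 8 and 1 adjusted over the list alone. Mdm2 (1.79 ± 0.14) and Cdkn1a (1.35 ± 0.12) were higher and Ei24 (-0.91 ± 0.11) lower (camera adjusted p = 0.000187, and adjusted p = 0.244 with an estimated correlation).

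Beside these groups, among stellate cell and matrix markers 9 of 11 measured members rose, 0 fell and 2 did not pass, against 10 and 0 adjusted over the list alone. Acta2 (1.80 ± 0.18), Col1a1 (1.04 ± 0.19) and Lum (1.09 ± 0.18) were higher, at a median of 0.63 (camera adjusted p = 0.00012, and adjusted p = 0.183 with an estimated correlation). For neutrophil markers 5 of 10 measured members rose, 0 fell and 5 did not pass, against 5 and 0 adjusted over the list alone (camera adjusted p = 0.00777, and adjusted p = 0.417 with an estimated correlation). Macrophage markers did not pass camera as a list (median 0.41, adjusted p = 0.0722, and 0.039635 by fry), and 6 of 17 measured members rose, 2 fell and 9 did not pass, against 7 and 3 adjusted over the list alone. Cd14 (3.04 ± 0.25) and Cd68 (1.56 ± 0.19) were among the higher ones. Liver endothelial markers did not pass camera either (median 0.29, adjusted p = 0.147, and 0.01779 by fry), and 4 of 9 measured members rose, 2 fell and 3 did not pass, against 5 and 3 adjusted over the list alone. Lyve1 (2.23 ± 0.19) was among the higher ones. Hepatocyte markers shifted down by a median of -0.39: 0 of 11 measured members rose, 7 fell and 4 did not pass, against 0 and 7 adjusted over the list alone. Tdo2 (-3.14 ± 0.39), tryptophan dioxygenase, and Apoh (-1.04 ± 0.10) were lower (camera adjusted p = 0.000373, and adjusted p = 0.156 with an estimated correlation). In the B and plasma cell list 0 of 6 measured members rose, 0 fell and 6 did not pass, against 0 and 0 adjusted over the list alone (camera adjusted p = 0.383). For pancreas and fat markers 0 of 7 measured members rose, 1 fell and 6 did not pass, against 0 and 3 adjusted over the list alone (camera adjusted p = 0.117), and for sex chromosome genes 0 of 4 measured members rose, 1 fell and 3 did not pass, against 0 and 1 adjusted over the list alone (camera adjusted p = 0.23).

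The effect of the receptor virus without hormone was set against the T3 response of Ad-GFP livers, to ask whether hormone-responsive genes moved the same or the opposite way. Of the genes called in both, 87 were higher with the virus label and lowered by T3, and 133 were lower with it and raised by T3, against 30.2 and 29.1 for independent lists. Same-direction genes were 34 higher and 65 lower in both, against 32.4 and 27.1. Thrsp (-2.01 ± 0.22 with the virus label, 1.89 ± 0.22 with T3) is among the 133. Across the 2930 genes called in either, r was -0.123 (Spearman -0.134, jackknife SE 0.101). Over all 22180 genes Pearson's r was -0.058 and Spearman's 0.055, so the rank correlation turned sign. Both comparisons share the Ad-GFP saline arrays, and unchanged groups simulated against them gave r = 0.502. The covariance over these 2930 genes was -0.0543 against 0.0105 in the simulation, and the difference of -0.0648 estimates it without the sharing. Over all genes the difference was -0.0134, and 54.4% of genes had the same sign in both effects, against 66.7% in the simulation. Sharing pushes both effects the same way, so it may add to the same-direction genes but not to the opposite ones. In the numbers of called genes its part was not separated, since with 3 shared arrays no split leaves 2 on each side. Opposite-direction genes numbered 118, 107 and 113 without Ad-GFP saline arrays 1, 2 and 3, rather than 220. Same-direction genes numbered 45 and 48 without Ad-GFP saline arrays 1 and 2 and 164 without labelled Ad-TRb T3 array 2, rather than 99.

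**Figure D3:**
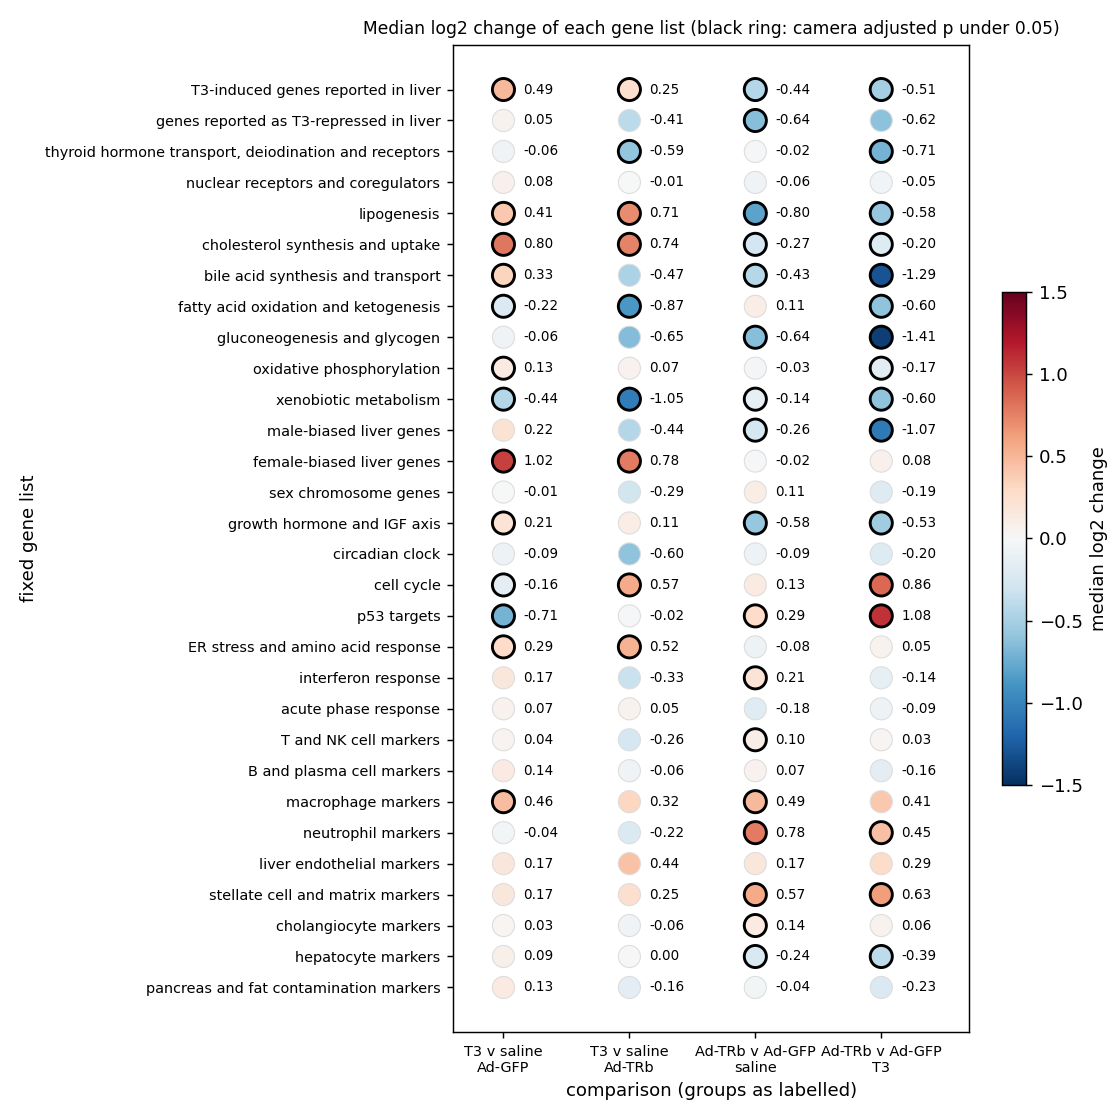
Median log2 change (colour and printed number) of 30 fixed gene lists (y axis) in the 4 pairwise comparisons (x axis), groups as labelled, with a black ring where camera's adjusted p was under 0.05. Bile acid genes have medians of 0.33, -0.47, -0.43 and -1.29, and cell cycle genes of -0.16, 0.57, 0.13 and 0.86.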

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

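Of the tests in this part, those of exchanged labels, of the probe set's position, of the share of hepatocytes, of regrouped residuals and of which arrays the high splits hold were chosen after the result was seen, and those of normalization and of other splits of the arrays before. Single outlying signals were not tested within groups of 3. Among whole arrays, labelled Ad-TRb T3 array 2 had the largest residual SD (0.197, against 0.107 to 0.17 in the others).

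The T3 response differed between livers labelled Ad-TRb and Ad-GFP livers, by the interaction test, for 3284 genes. Among the genes named, the log2 T3 effect was higher in livers labelled Ad-TRb for Sult1e1 (6.09), Cyp2b10 (5.37), Nradd (5.17), Cep126 (4.77), Tff2 (4.47) and Thrsp (1.70). It was lower for Sult3a1 (-5.69), Cyp3a25 (-5.05), Ces1f (-4.65), Slc22a30 (-4.57), Keg1 (-4.24), Cyp7a1 (-4.17), Thrb (-1.66), Me1 (-1.10) and Thra (-0.51). Keg1's other probe set gave -0.73. For the named gene lists the difference passed camera in 10. Of 100 splits of the 12 arrays into 4 groups of 3, 1 gave as many genes, the real one, with 2580 the highest of the others. This says little of the interaction itself, because 7364 genes had a main effect of virus or T3, and splits that mix these groups raise the residual variance. The bound set beforehand, fewer than 5 of 100 splits, was therefore wrong. The main effects were then fitted and only the residuals regrouped. Of 100 regroupings 1 gave as many genes, the real one, with 1016 the highest of the others. This is the smallest share that 100 regroupings can give. The residuals still hold any interaction, so mixing them raises the residual variance too. The result argues against chance for this number but does not exclude it. Among the other splits, the 2 that keep the 3 arrays labelled Ad-TRb with T3 in 1 group gave 2580 and 2350 genes while mixing the remaining arrays, and the highest of those that part these arrays was 99. Most of the number can therefore arise from that group standing apart, whatever the grouping of the others.

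For each pairwise comparison, 1 of the 10 splits of its 6 arrays gave as many genes, the real one, and 10 splits are too few for a share under 0.05. The real numbers were 1568 for T3 in Ad-GFP livers, 6908 for T3 in livers labelled Ad-TRb, 1681 between viruses under saline and 6552 between viruses under T3. The highest of the other splits was 0 in each, by limma with the 4-group fit; the numbers of the other splits at an unadjusted p are not given here, and those of the real ones under 0.05 were 4250, 8876, 4542 and 8624.

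The Thrb signal of livers labelled Ad-TRb was higher than in Ad-GFP livers under saline by 0.37, which did not pass, and lower under T3 by 1.29 on the log2 scale (-1.29 ± 0.13). An exchange of the virus labels of both T3 groups stays open. It would turn the sign of the virus effect under T3, which correlated across all genes with that under saline at r = 0.429, but this counts against it only if the receptor acts the same way with and without hormone, which no value here shows. Such an exchange would also mean that each T3 comparison set T3 and saline arrays of different viruses against each other. The numbers of genes called for T3 and for the interaction rest on the label as well. The position of the probe set stays open too, since 1 Thrb probe set was on the array and no probe positions are at hand. If it lies outside the delivered sequence, for example in an untranslated region, it may read the mouse's own Thrb alone, and its fall would then be a response of that gene to T3 in these livers.

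Livers labelled Ad-TRb differed from Ad-GFP livers under T3 for 6552 genes, 173 of them lower by at least 4-fold. Cyclic loess between arrays gave 6607 genes, 6079 of them among the 6552, so the number did not hang on adding this step. The values had already been normalized between arrays by RMA. A further normalization cannot show a change that RMA itself made, so that explanation stays open. A lower share of hepatocytes is argued against as the cause of the falls of at least 4-fold. The hepatocyte markers had a median of -0.39 (SD 0.89, 11 genes), and 1 of them fell that far. Alb, 1 of these markers, gave the highest signal of all arrays (17590), where changes may be read too small. The other markers were not checked for this, so a lower share of hepatocytes is not excluded for these falls. For smaller changes it stays open: the medians of stellate (0.63), macrophage (0.41) and endothelial (0.29) markers differ by 0.34, less than the mean SD of 0.77 within these lists, so a share of tissue that shifted from hepatocytes to these cells may account for part of them. The biological difference that the design names, the delivered receptor with its hormone, stays open and untested for both patterns, because the Thrb signal does not follow the label.

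Probe sets with no or several gene symbols, which no main comparison of the report uses, also passed in a fit and adjustment over every probe set. Of 10128 such probe sets, 284 (2.8%) passed for T3 in Ad-GFP livers, 1685 (16.6%) for T3 in livers labelled Ad-TRb, 294 (2.9%) between viruses under saline, 1452 (14.3%) between viruses under T3, and 561 (5.54%) for the interaction. The shares among all probe sets with 1 symbol were 6.07%, 29.1%, 6.39%, 27.5% and 12.9%.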

How the results depend on the processing

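No alternative of this part was added after the data were seen. In the named genes 5107 of 5227 values under other settings stayed on the same side of the threshold, 60 lost their call, 60 gained one and 0 reversed. With 1 array left out the numbers were 7634 of 8016, with 333 lost, 49 gained and 0 reversed. Direction was compared only for values called in the main fit or in the alternative. Naming genes for large changes or small p also favours calls that hold. Of the results that answer a comparison, 185 of 207 stayed alike under other settings, and 297 of 324 with 1 array left out. Numbers of genes were judged by the ratio given with the left-out arrays below, and correlations and slopes by their jackknife SE. That SE comes from the same fits with 1 array left out. Correlations and slopes therefore stay alike there almost by construction, and the 297 does not test them. The cause was not tested where none is given.

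Array weights raised the number of genes called to 3129 for T3 in Ad-GFP livers, 2544 between viruses under saline and 5044 for the interaction. They also brought the higher Thrb signal under saline past the threshold (0.46, adjusted p = 0.00914), where its other alternatives gave adjusted p from 0.0563 to 0.29. Requiring at least 1.5-fold left 763, 3304, 832 and 3193 genes in the 4 pairwise comparisons, in the report's order of T3 in Ad-GFP livers, T3 in livers labelled Ad-TRb, and viruses under saline and under T3, and adjusted p under 0.01 left 738 for T3 in Ad-GFP livers, 727 between viruses under saline and 1703 for the interaction, since both ask for more. Cyclic loess for T3 in Ad-GFP livers called 1673 genes, 1521 of them the same genes.

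The number of lists fell with an estimated correlation to 1, 0, 0 and 1 in the pairwise comparisons and 1 in the interaction. A list's own correlation does not account for all of this. Between viruses under saline, calls also ended for the T3-repressed list (estimated correlation 0.00235) and cholangiocyte markers (-0.0814), both below the preset 0.01. Fry called 18 lists for T3 in livers labelled Ad-TRb, 11 between viruses under saline and 5 for the interaction. With only genes at or above the median signal, 3, 10 and 6 lists passed in those 3 comparisons, where fewer genes were tested. Under median centring and cyclic loess the median log2 change of all genes was at most 0.057 in size. That value was for T3 in livers labelled Ad-TRb after median centring, against -0.023 as deposited. Of the 13, 9, 17, 16 and 10 lists called in the 5 comparisons 0 changed camera's direction. Lists that were not called were not checked.

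With each array left out in turn, T3 in Ad-GFP livers gave 914 to 2018 genes and viruses under saline 850 to 2166, while T3 in livers labelled Ad-TRb gave 5684 to 7047, viruses under T3 5485 to 6969 and the interaction 2406 to 3547. The lowest for T3 in livers labelled Ad-TRb came without labelled Ad-TRb saline array 1 and the lowest between viruses under T3 without Ad-GFP T3 array 1. For the other 3 comparisons it came without an Ad-GFP saline array, array 3 for the interaction. The numbers were 983, 934 and 914 without arrays 1, 2 and 3 for T3 in Ad-GFP livers (1016 and 1029 without Ad-GFP T3 arrays 1 and 2), and 878 and 850 without arrays 1 and 2 between viruses under saline (1066 without labelled Ad-TRb saline array 2). An array fewer leaves fewer degrees of freedom. Both T3 responses shared 621 to 1262 genes in direction and 32 to 87 against it. The virus effect under saline and the T3 response of Ad-GFP livers shared 45 to 164 and 107 to 325, and the virus effects under saline and T3 shared 481 to 1229 and 54 to 142. The arrays that move a number by more than 1.5 times are named with each comparison of the report.

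The labels do not say whether the replicate numbers pair the mice, and the data leave it unsettled, so the fits use no block. Of 18 pairs of arrays with the same number, 4 had a residual correlation over 0.1 (median 0.0495, from -0.022 to 0.155, against a median of -0.0255 for other pairs). Residuals cancel within a group, so the negative median of the other pairs follows from the positive one and adds no evidence. As a hint, 10 of 12 arrays correlated best with their own number. With the replicate number as a block, 1605, 7017, 1674 and 6645 genes passed in the pairwise comparisons and 3361 in the interaction. Signal over background limits the dim genes: 6039 of 22180 had a mean signal under 64, and 59 of these were among the 1568 called for T3 in Ad-GFP livers.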

Other observations

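The tests of the hypothesis at the end of this part were chosen after the result was seen.

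Members of the list of nuclear receptors and coregulators changed both ways. Camera did not call a shift of it, while fry called one down for T3 in livers labelled Ad-TRb (adjusted p = 0.0025525) and between viruses under T3 (adjusted p = 0.0014125). For T3 in livers labelled Ad-TRb 5 of 20 measured members rose, 6 fell and 9 did not pass, against 6 and 6 adjusted over the list alone (camera adjusted p = 0.39, fry's mixed test adjusted p = 2.13e-09). There Nr1i3 (-3.61 ± 0.19), the receptor CAR, Ppara (-1.84 ± 0.13), Nr5a2 (-1.49 ± 0.09) and Nr1h4 (-1.40 ± 0.14), the bile acid receptor FXR, fell. In Ad-GFP livers T3 lowered Nr1i3 (-1.42 ± 0.19), Nr1i2 (-0.63 ± 0.13) and Pparg (-1.68 ± 0.20). Between viruses under T3, Ppara was lower by 4.25-fold (-2.09 ± 0.13) and Nr1i3 by 6.31-fold (-2.66 ± 0.19) in livers labelled Ad-TRb. Circadian clock genes also moved both ways, more of them down. Fry called a shift down for T3 in livers labelled Ad-TRb (adjusted p = 0.048774) and between viruses under T3 (adjusted p = 0.025135), and camera did not. For T3 in livers labelled Ad-TRb 4 of 16 measured members rose, 8 fell and 4 did not pass, against 5 and 9 adjusted over the list alone (camera adjusted p = 0.227, fry's mixed test adjusted p = 2.35e-07). Nr1d1 (-1.95 ± 0.14), the repressor REV-ERB alpha, and Hlf (-1.36 ± 0.17) fell, while Bhlhe40 (1.67 ± 0.15) and Cry1 (0.94 ± 0.12) rose. In Ad-GFP livers Bhlhe41 (-1.97 ± 0.23) fell with T3. The hour at which each mouse was killed is not given in the sources used here, so a difference in hour between groups was not tested.

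Acute phase genes also went both ways: for T3 in livers labelled Ad-TRb 7 of 18 measured members rose, 4 fell and 7 did not pass, against 7 and 4 adjusted over the list alone (camera adjusted p = 0.306, fry's mixed test adjusted p = 6.06e-08). Fry's one-way test called a shift up there (adjusted p = 0.015301). Saa3 (3.34 ± 0.26) and Lbp (1.69 ± 0.13) rose, and Crp (-2.86 ± 0.20) and Itih3 (-1.59 ± 0.13) fell. Under T3, Lcn2 (3.49 ± 0.25), lipocalin 2, was 11.3-fold higher in livers labelled Ad-TRb than in Ad-GFP livers. Under saline Orm2 (1.91 ± 0.35) was higher there and Itih4 (-0.82 ± 0.10) lower.

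Genes that T3 raised in Ad-GFP livers were lower in livers labelled Ad-TRb under saline more often than genes of like signal, though most did not pass. Of the 811 genes raised by T3, 133 (16.4%) were lower past the threshold and 34 higher, with a median of -0.09. The share of 16.4% stands against a median of 5.92% and a highest of 9% in 10000 draws of genes matched on mean signal. The draws were not matched on the variance of a gene, and genes called for T3 may be called more readily in any comparison. Part of the excess may come from that, so the draws do not settle whether highly expressed genes fall in general. The median virus effect of these genes under saline lay below that of the 757 genes lowered by T3 (87 higher, 65 lower, median 0.03), with a difference of -0.12 on the log2 scale (permutation p = 1e-04, the smallest that 10000 draws can give, across genes, which are not independent). The shared Ad-GFP saline arrays push this difference the other way. It draws on the same genes and arrays in which the opposite directions had already been seen, so it is no separate support. A candidate explanation is that delivered receptor represses hormone-induced genes when hormone is scarce. Known targets were divided under saline: Thrsp was lower (-2.01), while Dio1 (-0.20) and Me1 (0.06) did not pass. Genes reported as T3-induced shifted down (camera adjusted p = 0.000175). Those reported as T3-repressed did so too (camera adjusted p = 0.00159), which this explanation does not cover. The virus effect on these genes under T3 was not used, because it subtracts the Ad-GFP T3 arrays by which they were chosen as high, which alone pushes it down. The explanation rests on the virus label, which the Thrb signal leaves open, and liver injury or a changed share of cell types in these livers was not separated from it.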
